A study of Homo sapiens with 28 samples.

How the data were processed

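RNA was sequenced from 28 libraries of primary normal human lung fibroblasts, with an oligo-dT directional library preparation per the labels' protocols. The labels give 8 groups in 2 experiments. In the siRNA experiment, cells transfected with an ON-TARGETplus control siRNA or siRNA against ATF4 were left untreated or given TGF-beta, in 3 libraries per group. In the Torin1 experiment, cells that were not transfected were untreated or received TGF-beta, Torin1, or both, in 4 libraries per group. Per the labels' protocols, the culture medium held 0.1% bovine serum albumin, 5.5 mM glucose, 2 mM glutamine and 1 mM pyruvate, growth in it lasted 24 h, and Torin1 was added 30 min before TGF-beta. The dose of TGF-beta and the length of exposure are not given in the sources used here. The treatment tags of 3 TGFb_Torin1 libraries name other compound numbers than their titles and the protocol do. These libraries were grouped by title.

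The authors quantified transcripts with Salmon 1.10.1 per the submitters' processing notes, and the deposited files list an estimated count (NumReads) and a TPM for each of 251955 transcripts per library. The estimated read counts were tested. The deposited TPM values, which Salmon scales by effective transcript length and to a fixed total, served only as weights for the mean transcript length of a gene in 1 alternative fit. The annotation release, the strandedness setting and the mapping mode of Salmon are not given in the sources used here. The effective length of a transcript was the same in every file. Transcript identifiers without version numbers were matched to GENCODE release 29 on GRCh38. The match covered 201667 transcripts in 58090 genes and between 92.49% and 93.53% of the estimated reads of each library. Transcripts outside that release were left out of the gene values and tested on their own. Estimated counts were summed per gene and rounded. Some genes had reads in some libraries and close to 0 in others of the same group. Such genes have large standard errors, which are given where their fold changes are, and some are given by their levels alone. Group means of the share of reads in matched transcripts ran from 92.53% in siControl to 93.46% in TGFb.

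The experiments were fitted separately because nothing in the labels links their batches. Within each experiment, 1 model with a mean per group was fitted to all libraries by edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter and quasi-likelihood F tests. p-values were adjusted by Benjamini and Hochberg over the tested genes, 14486 in the siRNA experiment and 15880 in the Torin1 experiment, and a gene was called changed at an adjusted p under 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. Levels are CPM, read counts scaled to a common library size, on the TMM scale. Main effects compare 2 groups, and an interaction is the effect of TGF-beta with the siRNA or inhibitor minus its effect without. The tests, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names, in each comparison, the 6 raised and 6 lowered genes of largest fold change among called genes that have a symbol, at least 5 CPM in 1 of the groups compared and, outside the interactions, no overlap between the libraries of those groups. It leaves XIST and genes on the Y chromosome out of that choice. It also names up to 4 members with the smallest adjusted p of each list described, and a fixed panel of 24 genes. Not every gene that the rule names is reported. Where every library of a group had only 0 to 3 counts of a gene, levels are given without a fold, as for some genes with reads in 1 library of a group alone.

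Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, with an estimated correlation beside it, and with fry. camera compares a list with the other genes, and fry asks whether the genes of a list move, on balance, one way. p-values were adjusted over the 31 lists that had at least 2 tested genes. Members called changed are counted over all genes and adjusted over the list alone. Overlaps between lists from the separate experiments, which share no library, were tested with 2-sided Fisher exact tests on the genes tested in both.

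The fit was tested on simulated data before the real data. Negative binomial counts were drawn with the library sizes and dispersions of the real libraries and the gene means of the untreated group in every group, and genes of at least 5 CPM were changed by known factors in the TGF-beta group. For TGF-beta in siControl cells it recovered 41.8% of 1.5-fold, 83.6% of 2-fold and 97.0% of 4-fold changes with 14047 genes tested, and 3.9% of its calls were false. For TGF-beta in the Torin1 experiment it recovered 77.6%, 95.5% and 100.0% with 15307 genes tested, and 3.2% of its calls were false. In each case 67, 67 and 66 genes were changed by these folds, far fewer than the 2914 and 9769 called in the real data. How these shares move when many genes change was not tested.

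Of the alternatives, DESeq2 1.42.0 changed the test (Wald), the size factors and the filtering (independent filtering) together, and limma-voom changed the model and the test. The others were DESeq2 size factors in edgeR, no low-count filter, a stricter filter of at least 1 CPM in as many libraries as 1 group holds, a minimum fold change of 2, offsets from the mean effective transcript length of each gene per library, the replicate number as a block, a fit to only the groups compared, and leaving out each library in turn. Because transcript lengths were the same in every file, the length offsets hold only differences in the estimated mix of transcripts per gene. They do not take out a trend with length across genes. siATF4 replicate 3 stands apart from the other libraries of its group. It was kept in the model, and the fits without it that concern comparisons it does not belong to were added after the data were seen.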

Results

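The libraries come from primary normal human lung fibroblasts treated with TGF-beta, the growth factor that turns fibroblasts into contractile, matrix-secreting myofibroblasts. The siRNA experiment has 4 groups of 3 libraries (siControl, siControl_TGFb, siATF4 and siATF4_TGFb), and the Torin1 experiment has 4 groups of 4 libraries (UT for untreated, TGFb, Torin1 and TGFb_Torin1). ATF4 is a transcription factor of the integrated stress response, and Torin1 inhibits the kinase mTOR. The files held 9.6 to 12.4 M estimated reads per library (median 10.85) in the siRNA experiment and 19.4 to 24.1 M (median 21.4) in the Torin1 experiment. The labels do not say whether the libraries of a group come from separate cultures or donors, so p-values measure only the spread between these libraries. Values after ± are standard errors of log2 fold changes or, with CPM, standard deviations over the libraries of a group. Of 12 fibroblast markers, 11 had a median over 1 CPM in each experiment (COL1A2, a collagen chain, 11600 CPM and 9280 CPM). Markers over 1 CPM numbered 1 of 12 epithelial, 1 of 10 endothelial, 2 of 12 leukocyte, 9 of 10 smooth muscle and pericyte and 1 of 8 mesothelial genes in the siRNA experiment, and 2, 2, 2, 9 and 1 in the Torin1 experiment. siATF4 replicate 3 stands apart: 2001 of 7779 genes lay over 0.5 log2 units from replicates 1 and 2, against at most 197 in a library of another siRNA group, and the difference ran with transcript length (Spearman -0.767 across genes, which are not independent replicates).

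**Figure D1:**
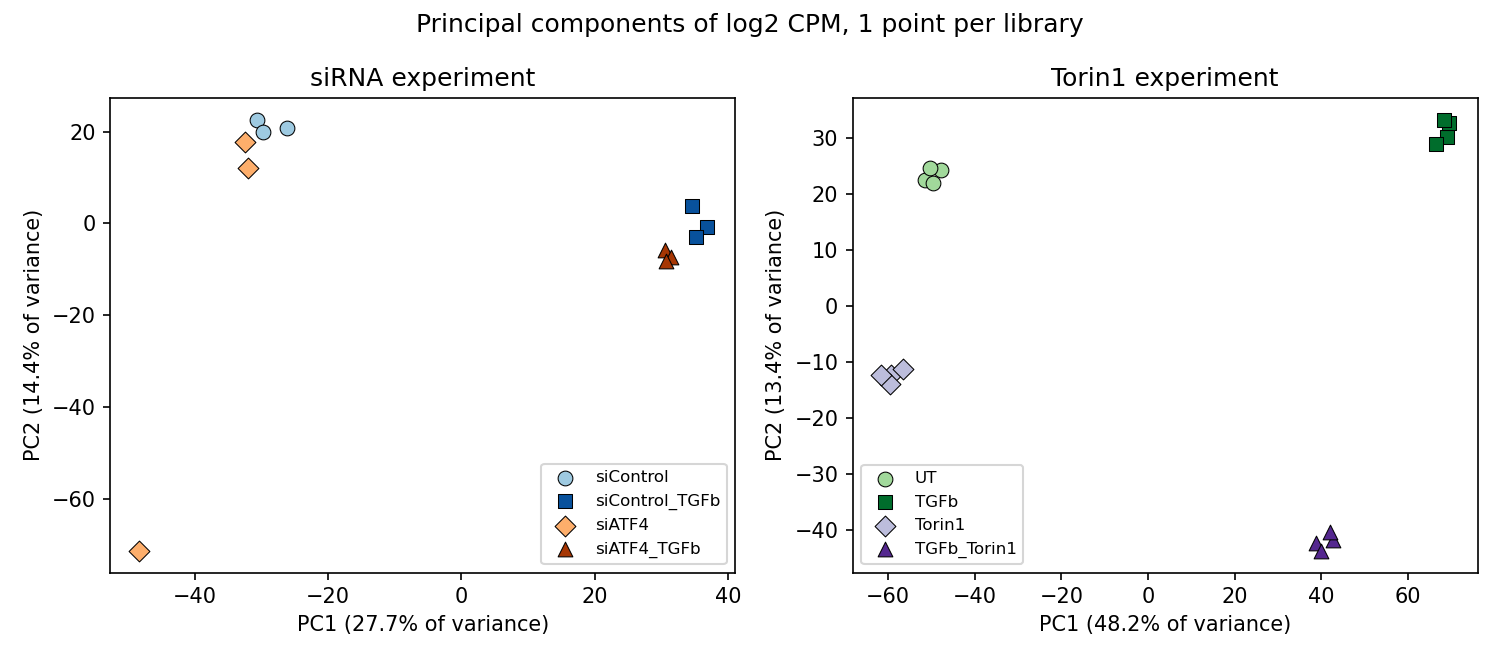
Principal components of log2 CPM in each experiment. Each point is a library coloured by group, and the axes give the share of variance, 27.7% and 14.4% in the siRNA experiment and 48.2% and 13.4% in the Torin1 experiment.

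ATF4 (chromosome 22, 39519695 to 39522685) was measured in every library of the siRNA experiment. Replicates 1, 2 and 3 had 35.0, 36.3 and 30.8 CPM in siControl, 50.8, 51.1 and 53.2 CPM in siControl_TGFb, 14.2, 20.5 and 19.1 CPM in siATF4, and 19.9, 16.2 and 13.7 CPM in siATF4_TGFb. ATF4 mRNA was lower with its siRNA without TGF-beta (-0.92 ± 0.15, adjusted p = 0.0387) and with it (-1.64 ± 0.15, adjusted p = 0.000436). Without TGF-beta the call was lost after leaving out siControl replicate 1, 2 or 3 or siATF4 replicate 1 (-1 to -0.79, adjusted p = 0.0622 to 0.149). In the Torin1 experiment ATF4 had 7.53 to 14.5 CPM per library.

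**Figure D2:**
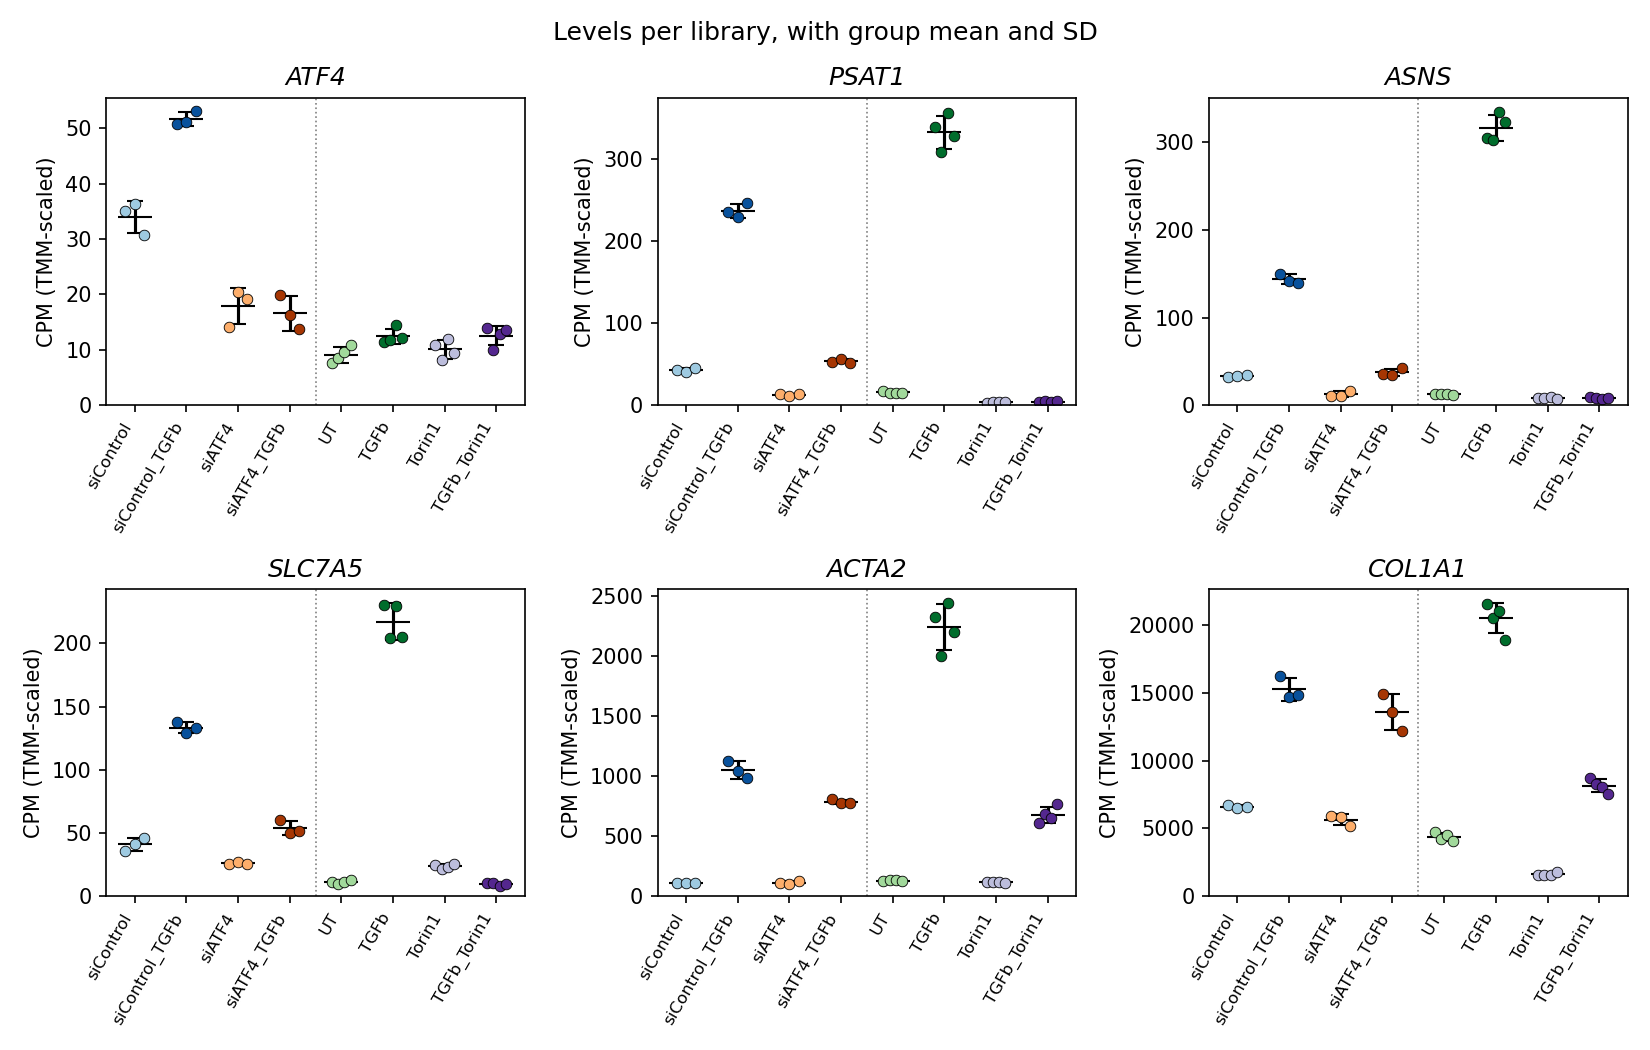
CPM of ATF4, PSAT1, ASNS, SLC7A5, ACTA2 and COL1A1 in every library of the 8 groups. Points are libraries, and lines are the group mean ± SD.

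In control siRNA cells, TGF-beta raised myofibroblast and matrix genes and a set of amino acid synthesis genes. ACTA2, the smooth muscle actin of myofibroblasts, rose by a log2 fold change of 3.20 ± 0.08 (n = 3 libraries per group), and ELN, which encodes elastin, rose by 7.57 ± 0.15, from 6.2 to 1180 CPM. Among the largest increases were also IGFBP3 (6.55 ± 0.21), which binds insulin-like growth factors, and PRG4 (6.07 ± 0.13), which encodes lubricin. COMP, a matrix protein, went from 0.0618 to 21.5 CPM, KCNH1, a potassium channel, from 0.124 to 10.4 CPM, and CRELD1 from 0.0618 to 5.15 CPM. ADH1B, an alcohol dehydrogenase, fell by 2.96 ± 0.10 in log2, GDF10, a TGF-beta family ligand, by 2.73 ± 0.11, the transporter gene SLC7A14 by 2.81 ± 0.19, and GUCY1A1, a guanylate cyclase subunit, by 3.20 ± 0.42. EVI5 (10.9 to 0.034 CPM) and MYSM1 (-3.08 ± 0.93, -3.74 without siControl_TGFb replicate 1) were also called lower, with near-absent values in single libraries. EVI5 lost its call after leaving out siControl replicate 1 or siControl_TGFb replicate 1, 2 or 3 (adjusted p = 0.0555 to 0.0966), and MYSM1 after leaving out any 1 of the 6 libraries compared (adjusted p = 0.0533 to 0.106).

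TGF-beta in control cells also raised CCN2 (2.35 ± 0.07), a direct target of TGF-beta signalling, COL1A1 (1.20 ± 0.08), a chain of collagen I, and FN1 (1.51 ± 0.21), fibronectin. Genes of serine synthesis rose, with PSAT1 at 2.48 ± 0.07 and PHGDH at 1.52 ± 0.10. So did SHMT2 (1.09 ± 0.09) and MTHFD2 (1.63 ± 0.14) of mitochondrial one-carbon metabolism. Genes that make asparagine and proline rose too: ASNS (2.10 ± 0.14), PYCR1 (1.14 ± 0.08) and ALDH18A1 (0.86 ± 0.05). The transporters SLC7A5 (1.69 ± 0.10), SLC7A11 (0.62 ± 0.12) and SLC2A1 (0.91 ± 0.13), and the stress response genes CHAC1 (1.57 ± 0.12), TRIB3 (1.49 ± 0.10) and DDIT4 (1.25 ± 0.23) rose. HIF1A (0.52 ± 0.12), of the hypoxia response, and ATF4 (0.60 ± 0.15, adjusted p = 0.0132) also rose, and ATF4 was not called without siControl replicate 3 (0.52, adjusted p = 0.0726). HK2 and MTOR were not called (adjusted p = 0.64 to 0.731). The test called 2914 genes changed, 1572 raised and 1342 lowered, of which 684 by at least 2-fold. Without siATF4 replicate 3, a library in neither group compared, the count was 4593 (2334 raised, 2259 lowered). It was 1361 with length offsets and 4463 with only these groups in the fit.

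Of the gene lists written in advance, camera called 14 of 31 in this comparison, and 10 held with an estimated correlation. Among 22 extracellular matrix genes, 19 rose and 2 fell by either count (median 1.51, camera adjusted p = 1.39e-14). They included BGN (3.01 ± 0.08), SPARC (1.33 ± 0.04) and POSTN (1.61 ± 0.06). Contractile genes rose in 15 of 20 cases, 17 adjusted over the list alone (camera adjusted p = 1.39e-14). Among them were the actin filament genes TPM1 (2.91 ± 0.07), TAGLN (3.08 ± 0.10) and CALD1 (1.5 ± 0.06). TGF-beta and SMAD targets rose in 13 of 19 cases, 13 adjusted over the list alone (camera adjusted p = 5.71e-13), with NOX4, an oxidase, at 5.13 ± 0.18 and ADAM12 at 2.67 ± 0.12. Of 20 collagen-modifying enzymes and chaperones, 12 rose and 1 fell, 13 and 1 adjusted over the list alone (camera adjusted p = 1.55e-05), with the hydroxylases P4HA1 (1.01 ± 0.06) and P3H1 (1.05 ± 0.08). Serine, glycine and one-carbon genes rose in 7 of 12 cases and fell in 1, 8 and 1 adjusted over the list alone (camera adjusted p = 8.12e-05), including MTHFD1L (0.89 ± 0.07). Proline, asparagine and glutamate genes gave 7 raised and 1 lowered of 12 by either count (camera adjusted p = 7.99e-05), with GOT1, an aspartate aminotransferase, at 0.94 ± 0.07. Amino acid transporters rose in 9 of 14 cases by either count (camera adjusted p = 3.95e-05). SLC1A4 (1.65 ± 0.10), SLC7A1 (1.43 ± 0.11) and SLC38A1 (0.99 ± 0.10) were among them. Aminoacyl-tRNA synthetases, which load amino acids onto tRNAs, rose in 13 of 20 cases, 15 adjusted over the list alone (camera adjusted p = 6.89e-09). MARS1 rose by 0.87 ± 0.06 and EPRS1 by 0.72 ± 0.06. Stress targets of the integrated stress response gave 10 raised and 1 lowered of 20, 12 and 1 adjusted over the list alone (camera adjusted p = 3.77e-05, adjusted p = 0.11 with an estimated correlation). Endoplasmic reticulum chaperones gave 6 of 17 raised, 8 adjusted over the list alone (camera adjusted p = 0.000521, adjusted p = 0.115 with an estimated correlation).

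Without TGF-beta, the ATF4 siRNA lowered PSAT1 and PHGDH of serine synthesis, ASNS of asparagine synthesis and 5 of 14 amino acid transporters. PSAT1 fell by 1.72 ± 0.08 in log2 (42.5 to 12.9 CPM, n = 3 libraries per group), ASNS by 1.40 ± 0.15 (33.6 to 12.6 CPM) and PHGDH by 1.29 ± 0.11 (60.1 to 24.5 CPM). CHAC1 (-1.23 ± 0.13), CBS (-1.21 ± 0.09), a cysteine synthesis enzyme, TRIB3 (-0.85 ± 0.10), SLC7A1 (-0.92 ± 0.11), WARS1 (-0.39 ± 0.05) and ACTG2 (-0.72 ± 0.08), a smooth muscle actin, were lower. SLC7A5 (-0.65 ± 0.10), SLC38A1 (-0.68 ± 0.10), SLC1A4 (-0.60 ± 0.10), AFDN (-1.33 ± 0.21), BGN (-0.49 ± 0.08), MARS1 (-0.41 ± 0.06) and XPOT (-0.39 ± 0.06), a tRNA exporter, were called lower as well. So was the glycine transporter SLC6A9, from 9.23 to 0.427 CPM, with all of its siATF4 reads in replicate 1 and 0 in replicates 2 and 3, so no fold is given. GBE1 (0.34 ± 0.05), of glycogen synthesis, CDKN1A (0.44 ± 0.08), an inhibitor of the cell cycle, and the NRF2 targets SRXN1 (0.42 ± 0.07) and NQO1 (0.52 ± 0.09) were called higher. The remaining gene called higher was ENSG00000256500, at 0 CPM in siControl and 10.7 ± 5.03 CPM in siATF4, which has no symbol and was chosen after its values were seen. Calls of AFDN, BGN, CDKN1A, GBE1, NQO1, SLC1A4, SLC38A1, SLC6A9, SRXN1 and XPOT were lost after leaving out siControl replicate 1, 2 or 3 (adjusted p over these genes 0.0539 to 0.212). Leaving out siATF4 replicate 2 also ended those of BGN, CDKN1A, GBE1, SLC1A4, SLC38A1, SLC6A9 and SRXN1. SLC7A5 lost its call after leaving out siControl replicate 2 or 3 or siATF4 replicate 1 (adjusted p = 0.0663 to 0.102), and MARS1 after siControl replicate 1 or 3 (adjusted p = 0.0712 to 0.0779). With length offsets MARS1 turned to 0.35 (adjusted p = 0.827). MTHFD2, PYCR1, SHMT2, ALDH18A1, SLC7A11, SLC2A1, HK2, DDIT4, HIF1A, MTOR, ACTA2, COL1A1, FN1 and CCN2 were not called (adjusted p = 0.0589 to 1).

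The test called 45 genes, 5 raised and 40 lowered, 11 of them by at least 2-fold. The count was 233 (31 raised, 202 lowered) without siATF4 replicate 3, 20, 20 and 18 without siControl replicates 1, 2 and 3, 1 with only these groups in the fit, 11 with length offsets, and 220 (48 raised, 172 lowered) in DESeq2. Fold changes in this comparison ran with transcript length (Spearman -0.625 across genes), with a median of 0.177 in the shortest 20% of genes and -0.176 in the longest. The length offsets do not take out this trend, so the count with them is not one corrected for it. Camera called 14 of 31 lists and 3 held with an estimated correlation. Amino acid transporters fell in 5 of 14 cases, 6 adjusted over the list alone (median -0.31, camera adjusted p = 1.38e-07). Contractile genes gave 1 lowered of 20, 7 adjusted over the list alone (median -0.34, camera adjusted p = 1.38e-07). Of 20 collagen-modifying genes, 7 were lower adjusted over the list alone (camera adjusted p = 0.000199), while edgeR called none of them over all genes (lowest adjusted p = 0.0594, for LOX). Serine, glycine and one-carbon genes gave 2 lowered of 12, 5 lowered and 1 raised adjusted over the list alone (camera adjusted p = 0.00156, adjusted p = 0.0569 with an estimated correlation). Extracellular matrix genes gave 1 lowered of 22, 6 adjusted over the list alone (camera adjusted p = 4.08e-07, adjusted p = 0.243 with an estimated correlation). Stress targets gave 4 lowered of 20, 7 lowered and 1 raised adjusted over the list alone (camera adjusted p = 0.00435, adjusted p = 0.309 with an estimated correlation). NRF2 targets, which act against oxidants, gave 2 raised of 14, 7 adjusted over the list alone (camera adjusted p = 1.38e-07, adjusted p = 0.164 with an estimated correlation). For cytosolic ribosomal proteins camera gave an upward call (median 0.13, adjusted p = 0.0423, adjusted p = 0.717 with an estimated correlation), which turned downward without siATF4 replicate 3 (adjusted p = 1.11e-07).

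**Figure D3:**
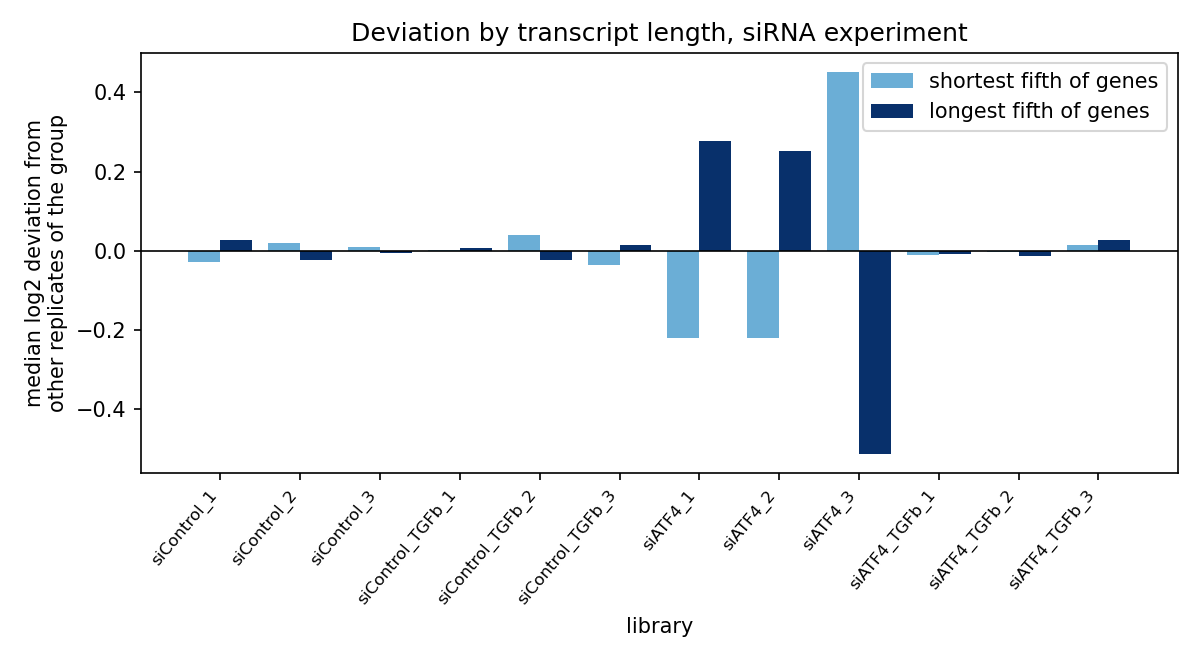
Median log2 deviation of each siRNA library from the other libraries of its group, for the shortest and the longest 20% of genes by transcript length. siATF4 replicate 3 is at 0.451 and -0.512.

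Under TGF-beta, the ATF4 siRNA lowered serine, asparagine and one-carbon genes, amino acid transporters and stress response genes. PSAT1 fell by 2.15 ± 0.07 in log2 (237 ± 8.69 to 53.4 ± 2.28 CPM, n = 3 libraries per group), ASNS by 1.95 ± 0.14 (144 to 37.3 CPM), PHGDH by 1.75 ± 0.10 (172 to 51.1 CPM), and PCK2, a mitochondrial enzyme of gluconeogenesis, by 2.07 ± 0.10 (69.5 to 16.5 CPM). MTHFD2 (-1.25 ± 0.14), SHMT2 (-0.63 ± 0.09), PYCR1 (-0.60 ± 0.08), CHAC1 (-1.67 ± 0.12), TRIB3 (-1.30 ± 0.10) and SLC7A5 (-1.30 ± 0.09) were lower. So were INHBE, an inhibin subunit (-2.88 ± 0.50, 15 to 2.04 CPM), ADM2, a peptide hormone (-2.41 ± 0.40, 9.28 to 1.74 CPM), and ACTA2 (-0.41 ± 0.07, adjusted p = 0.0303). The 6 genes called higher were ANKDD1A (0.57 ± 0.10), NPTX1 (0.53 ± 0.10), CPNE1 (0.37 ± 0.07), BTG2 (0.35 ± 0.07), KLHL21 (0.35 ± 0.07) and GBE1 (0.27 ± 0.05). DDIT4, SLC7A11, CCN2, FN1, COL1A1, HIF1A, HK2, ALDH18A1, SLC2A1 and MTOR were not called (adjusted p = 0.0795 to 0.997). INHBE, ADM2, ACTA2, ANKDD1A, BTG2 and GBE1 lost their calls after leaving out any 1 of the 6 libraries compared (adjusted p over these genes 0.0503 to 0.243). CPNE1 lost its call after leaving out any of them but siATF4_TGFb replicate 2, and NPTX1 and KLHL21 any but siATF4_TGFb replicate 3 (adjusted p over the 3 genes 0.084 to 0.271). SHMT2 was not called without siATF4_TGFb replicate 2 (-0.60, adjusted p = 0.0514).

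The test called 105 genes, 6 raised and 99 lowered, 21 of them by at least 2-fold. The count was 44, 42 and 52 without siControl_TGFb replicates 1, 2 and 3, 49, 48 and 57 without siATF4_TGFb replicates 1, 2 and 3, and 589 (181 raised, 408 lowered) without siATF4 replicate 3, which is in neither group. It was 363 (80 raised, 283 lowered) with only these groups in the fit, 35 with length offsets, and 232 (33 raised, 199 lowered) in DESeq2. Camera called 10 of 31 lists and 6 held with an estimated correlation. Stress targets fell in 7 of 20 cases, 15 adjusted over the list alone (median -0.51, camera adjusted p = 2.25e-18), including CBS (-1.75 ± 0.09) and STC2 (-0.61 ± 0.05). Amino acid transporters fell in 5 of 14 cases, 7 adjusted over the list alone (camera adjusted p = 4.66e-09). SLC1A5 (-0.96 ± 0.06), SLC1A4 (-1.15 ± 0.10) and SLC7A1 (-0.90 ± 0.10) were lower. Serine, glycine and one-carbon genes fell in 4 of 12 cases, 6 lowered and 1 raised adjusted over the list alone (camera adjusted p = 1.31e-08). Proline, asparagine and glutamate genes fell in 4 of 12 cases, 5 lowered and 1 raised adjusted over the list alone (camera adjusted p = 1.47e-07). The aminotransferases GPT2 (-0.95 ± 0.10) and GOT1 (-0.61 ± 0.07) were lower. Collagen-modifying genes fell in 3 of 20 cases, 11 adjusted over the list alone (camera adjusted p = 4.66e-09). The 3 were LOX, LOXL3 and SERPINH1, and each lost its call after leaving out any 1 of the 6 libraries compared (adjusted p = 0.0648 to 0.226). Contractile genes fell in 3 of 20, 9 adjusted over the list alone (camera adjusted p = 1.31e-08). Besides ACTA2 these were the integrin gene ITGA11, which fell by 1.24 ± 0.14, and ACTG2, which lost its call after leaving out any of the 6 but siControl_TGFb replicate 3 (adjusted p = 0.0578 to 0.105). Aminoacyl-tRNA synthetases fell in 6 of 20 cases, 8 adjusted over the list alone (camera adjusted p = 3.47e-07, adjusted p = 0.0503 with an estimated correlation). WARS1 fell by 0.77 ± 0.05, CARS1 by 0.53 ± 0.06 and MARS1 by 0.51 ± 0.06. The 6 became 3 or 4 after leaving out 1 of the libraries compared, and EPRS1 lost its call without any of them but siATF4_TGFb replicate 3 (adjusted p = 0.0527 to 0.072). Extracellular matrix genes gave 2 lowered of 22, 5 adjusted over the list alone (camera adjusted p = 1.65e-05, adjusted p = 0.251 with an estimated correlation). BGN lost its call after leaving out any of the 6 libraries (adjusted p = 0.0932 to 0.273), and COL1A2 any but siControl_TGFb replicate 3 (adjusted p = 0.0987 to 0.243). Endoplasmic reticulum chaperones gave 1 lowered of 17, 5 adjusted over the list alone (camera adjusted p = 1.65e-05, adjusted p = 0.0756 with an estimated correlation). The 1 was HERPUD1, which lost its call after leaving out any of the 6 (adjusted p = 0.0556 to 0.105). Without siATF4 replicate 3 the lowered genes were 10 collagen-modifying, 12 contractile, 7 matrix and 5 chaperone genes. Lists of glycolysis, the tricarboxylic acid cycle and oxidative phosphorylation were not called by camera (adjusted p = 0.0883 to 0.0969).

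In ATF4 siRNA cells, TGF-beta still raised the myofibroblast genes. ACTA2 rose by 2.78 ± 0.08 in log2 (n = 3 libraries per group), CCN2 by 2.31 ± 0.07, FN1 by 1.62 ± 0.21 and COL1A1 by 1.26 ± 0.08. ELN (7.08 ± 0.15), IGFBP3 (6.58 ± 0.21), NOX4 (5.75 ± 0.19) and PRG4 (5.70 ± 0.13) rose, and COMP went from 0.134 to 14 CPM. PSAT1 (2.04 ± 0.08), ASNS (1.55 ± 0.15), MTHFD2 (1.16), CHAC1 (1.13 ± 0.13), PHGDH (1.06 ± 0.11), SLC7A5 (1.04 ± 0.10), TRIB3 (1.04 ± 0.10), PYCR1 (0.98 ± 0.09), ALDH18A1 (0.93 ± 0.05), SHMT2 (0.74 ± 0.09), SLC2A1 (0.65 ± 0.13) and HIF1A (0.43) rose. HIF1A lost its call without siATF4_TGFb replicate 1, 2 or 3 (adjusted p = 0.0503 to 0.067). ADH1B (-3.25 ± 0.10), GUCY1A1 (-2.76 ± 0.42), ADGRD1, an adhesion receptor (-2.71 ± 0.33), and GDF10 (-2.42 ± 0.11) fell. SLC25A15, a mitochondrial ornithine carrier, was listed at 0 CPM in siATF4 and 13.7 CPM in siATF4_TGFb, and URGCP-MRPS24, a read-through gene, at 12.8 CPM and 0. URGCP-MRPS24 lost its call after leaving out any 1 of the 6 libraries compared (adjusted p = 0.0508 to 0.0927), and TAF2, a transcription factor subunit (-2.38 ± 0.68), after leaving out siATF4 replicate 3 or any siATF4_TGFb replicate (adjusted p = 0.054 to 0.0785). ATF4, HK2, DDIT4, SLC7A11 and MTOR were not called (adjusted p = 0.158 to 0.86). The test called 3050 genes, 1598 raised and 1452 lowered, 657 of them by at least 2-fold, and 1405 with length offsets or 1517 with only these groups in the fit. Fold changes here also ran with transcript length (Spearman 0.296 across genes), with a median of -0.124 in the shortest 20% of genes and 0.164 in the longest. Matrix genes gave 19 raised and 2 lowered of 22 by either count (camera adjusted p = 2.48e-16, adjusted p = 0.0512 with an estimated correlation). Contractile genes gave 16 of 20 raised, 17 adjusted over the list alone (camera adjusted p = 2.43e-16). TGF-beta and SMAD targets gave 14 raised and 1 lowered of 19, 14 and 2 adjusted over the list alone (camera adjusted p = 2.5e-11). Stress targets gave 6 raised and 2 lowered of 20, 8 and 3 adjusted over the list alone, which camera did not call (adjusted p = 0.193).

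Testing whether the TGF-beta effect itself differed with the ATF4 siRNA called 2 genes. SLC1A5, a glutamine transporter, went from 219 to 273 CPM in control cells and from 181 to 140 CPM in ATF4 siRNA cells (interaction -0.69 ± 0.08, adjusted p = 0.0392, n = 3 libraries per group). The other, chosen after its values were seen, was ENSG00000256500, with 15.27 ± 3.78 CPM in siControl_TGFb, 10.7 ± 5.03 CPM in siATF4 and 0 CPM in siControl and siATF4_TGFb. SLC1A5 lost its call after leaving out any library but siATF4 replicates 2 and 3 (adjusted p = 0.0561 to 0.285). The panel genes reported here were uncalled (adjusted p = 0.706 to 0.964), among them SLC7A5 (-0.65 ± 0.14), PSAT1 (-0.43 ± 0.10) and ACTA2 (-0.42 ± 0.10). At an unadjusted p under 0.05 there were 658 of the 14486 tested genes, no more than chance alone would give. How well this test recovers a true difference was not simulated. The low count therefore does not show that the TGF-beta effect was the same with both siRNAs. DESeq2 called 17 (3 raised, 14 lowered) and limma-voom 0, and edgeR without a low-count filter called 1. The count was 1 without siControl replicate 1 or 2, 0 without siControl_TGFb replicate 1, 2 or 3, 1 without siATF4 replicate 1, 8 without siATF4 replicate 3, 0 without siATF4_TGFb replicate 1 and 1 without siATF4_TGFb replicate 3. Camera gave downward calls for the stress targets (7 of 20 lower adjusted over the list alone and none called over all genes, adjusted p = 2.33e-09), which were lost with an estimated correlation (adjusted p = 0.13), as were all of its 9 calls. Fold changes of this interaction also ran with transcript length (Spearman 0.578 across genes).

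In the Torin1 experiment, TGF-beta raised the same named myofibroblast genes and amino acid synthesis genes by larger log2 fold changes. CCN2 rose by 4.76 ± 0.05, ACTA2 by 4.10 ± 0.07 (131 to 2240 CPM, n = 4 libraries per group), COL1A1 by 2.22 ± 0.06 (4390 to 20500 CPM) and FN1 by 2.00 ± 0.08. ASNS rose by 4.64 ± 0.07 (12.7 ± 0.617 to 316 ± 15.2 CPM), PSAT1 by 4.42 ± 0.08 (15.5 to 332 CPM), SLC7A5 by 4.26 ± 0.08 (11.3 to 217 CPM), MTHFD2 by 4.09 ± 0.09 and CHAC1 by 3.80 ± 0.11. TRIB3 (2.96 ± 0.06), PYCR1 (2.57 ± 0.04), PHGDH (2.5 ± 0.05), ALDH18A1 (1.97 ± 0.03), SHMT2 (1.67), DDIT4 (1.56), SLC2A1 (1.16), HIF1A (0.95), SLC7A11 (0.48), ATF4 (0.45 ± 0.14, adjusted p = 0.011) and MTOR (0.29 ± 0.12) rose. MTOR lost its call without UT replicate 2, 3 or 4 or TGFb replicate 1, 3 or 4 (adjusted p = 0.0565 to 0.136). HK2 (-0.61), a glycolysis enzyme, fell. The largest increases included IGF1, a growth factor (9.32 ± 0.21, 0.11 to 75.9 CPM), TSPAN2, a membrane protein (8.89 ± 0.12), PRG4 (8.72 ± 0.18) and IGFBP3 (8.63 ± 0.17). MDFI went from 0.011 to 29.6 CPM and TYRP1 from 0.0106 to 9.88 CPM. ADH1A went from 5.38 to 0.0553 CPM and BCL2A1, which acts against cell death, from 5.24 to 0.056 CPM. The alcohol dehydrogenase ADH1B (-5.89 ± 0.08), THBD, which encodes thrombomodulin (-5.88 ± 0.31), the nuclear receptor NR4A3 (-5.02 ± 0.14) and the adenosine receptor ADORA2A (-4.56 ± 0.78, -5.23 without TGFb replicate 4) fell. The test called 9769 genes, 4883 raised and 4886 lowered, 2952 of them by at least 2-fold.

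Camera called 14 of 31 lists for TGF-beta in this experiment, and 12 held with an estimated correlation. All 20 contractile genes rose by either count (camera adjusted p = 2.09e-12), and matrix genes gave 20 raised and 2 lowered of 22 (median 2.39, adjusted p = 6.47e-11), counts that were the same adjusted over the list alone. Also the same by both counts were collagen-modifying genes (18 raised, 1 lowered of 20, adjusted p = 1.73e-08), SMAD targets (16 and 1 of 20, adjusted p = 5.11e-09), aminoacyl-tRNA synthetases (18 and 1 of 20, adjusted p = 9.65e-09), endoplasmic reticulum chaperones (17 of 17 raised, adjusted p = 5.11e-09) and ribosome biogenesis genes (18 of 20 raised, adjusted p = 7.87e-07). Serine genes (8 and 3 of 12, adjusted p = 0.00363), proline genes (10 and 2 of 12, adjusted p = 0.000227), stress targets (14 and 4 of 20, adjusted p = 0.00155) and nucleotide synthesis genes (13 and 1 of 16, adjusted p = 0.000197) were also the same adjusted over the list alone. Transporters gave 11 raised and 2 lowered of 14 by either count (adjusted p = 0.000206, adjusted p = 0.0742 with an estimated correlation). Lysosome and autophagy genes moved down (5 raised, 19 lowered of 29 by either count, adjusted p = 0.00665). Targets of FOXO, transcription factors of growth arrest, also did (2 and 10 of 15, 2 and 11 adjusted over the list alone, adjusted p = 0.000367, adjusted p = 0.0742 with an estimated correlation). FBXO32, a ligase of protein degradation, fell by 2.52 ± 0.04. Lists not called by camera, with the same counts adjusted over the list alone, were glycolysis (11 raised, 8 lowered of 20, adjusted p = 0.427), pentose phosphate (2 and 4 of 8, 0.335), tricarboxylic acid cycle (6 and 5 of 20, 0.684, with median 0.01 and mean -0.09), oxidative phosphorylation (5 and 8 of 26, 0.581), fatty acid synthesis (3 and 6 of 12, 0.581), hypoxia targets (4 and 5 of 14, 0.626), NRF2 targets (4 and 8 of 14, 0.0649) and cell cycle genes (2 and 7 of 20, 0.278). So were inflammatory genes (6 and 4 of 15, 0.556), interferon-stimulated genes (1 and 4 of 15, 0.242) and markers of fibroblasts (3 and 7 of 11, 0.339), epithelium (1 and 1 of 3, 0.719), endothelium (1 and 3 of 5, 0.339), leukocytes (0 and 1 of 2, 0.339) and smooth muscle and pericytes (6 and 3 of 10, 0.26). Cholesterol synthesis gave 7 and 11 of 23, 7 and 12 adjusted over the list alone (adjusted p = 0.335), and ribosomal proteins 2 and 6 of 32, 2 and 4 adjusted over the list alone (adjusted p = 0.635).

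Torin1 alone, without TGF-beta, lowered PSAT1 and COL1A1 and raised SLC7A5. PSAT1 fell by 2.16 ± 0.11 in log2 (15.5 to 3.45 CPM, n = 4 libraries per group) and COL1A1 by 1.41 ± 0.06 (4390 to 1650 CPM), and SLC7A5 rose by 1.08 ± 0.09. DDIT4 (-1.20 ± 0.10), MTHFD2 (-0.67 ± 0.10), ASNS (-0.62 ± 0.08), PHGDH (-0.43 ± 0.05), PYCR1 (-0.28 ± 0.04) and ALDH18A1 (-0.16) fell. CCN2 (0.81 ± 0.04), CHAC1 (0.69), HK2 (0.65), SLC7A11 (0.58 ± 0.06), TRIB3 (0.32), FN1 (0.22) and HIF1A (0.14) rose. FN1 lost its call without UT replicate 2, 3 or 4 or Torin1 replicate 1 or 4 (adjusted p = 0.0862 to 0.128), and HIF1A without UT replicate 2 or 3 or Torin1 replicate 1 (adjusted p = 0.054 to 0.0651). MTOR, SLC2A1, ACTA2, SHMT2 and ATF4 were not called (adjusted p = 0.0656 to 0.463). The largest increases were of DLL4, a Notch ligand (2.18 ± 0.14), RGS9, a regulator of G proteins (2.10 ± 0.06), MYBL1 (2.06 ± 0.09), the hormone gene STC1 (1.96 ± 0.09), DNER (1.96 ± 0.18) and the protease ADAMTS1 (1.94 ± 0.53). PIK3R3, a kinase subunit (-1.72 ± 0.08), and RFX5, a transcription factor (-1.63 ± 0.05), fell. CCN1 (5.24 to 0.128 CPM) and AIMP1 (7.66 to 0.747 CPM) were called lower, with all of their reads in the Torin1 group in replicate 2 and 0 in replicates 1, 3 and 4, so no fold is given. KIAA0586 (-1.78 ± 0.64, -2.54 without Torin1 replicate 1) was called lower with a large error. It lost its call without UT replicate 1, 3 or 4 or Torin1 replicate 2 or 3 (adjusted p = 0.0555 to 0.0984). The test called 5978 genes, 2870 raised and 3108 lowered, of which 378 by at least 2-fold, and 3739 with length offsets. Camera called 11 of 31 lists, none of which held with an estimated correlation. Endoplasmic reticulum chaperones gave 1 raised and 13 lowered of 17 by either count (camera adjusted p = 3.78e-05, adjusted p = 0.131 with an estimated correlation), with CALR, a calcium-binding chaperone, at -0.59 ± 0.03. Collagen-modifying genes gave 3 and 11 of 20, 3 and 12 adjusted over the list alone (camera adjusted p = 0.00533, adjusted p = 0.251 with an estimated correlation). Contractile genes gave 2 and 13, 2 and 14 adjusted over the list alone (camera adjusted p = 0.00533, adjusted p = 0.299 with an estimated correlation). Ribosomal proteins gave 14 raised of 32, 21 adjusted over the list alone (camera adjusted p = 0.00284, adjusted p = 0.583 with an estimated correlation).

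Under TGF-beta, Torin1 lowered amino acid synthesis genes strongly. PSAT1 fell by 6.23 ± 0.10 in log2 (332 to 4.42 CPM, n = 4 libraries per group), ASNS by 5.26 ± 0.08 (316 to 8.26 CPM), SLC7A5 by 4.48 ± 0.09 (217 to 9.71 CPM), DDIT4 by 4.36 ± 0.12, MTHFD2 by 3.86 ± 0.09, TRIB3 by 3.63 ± 0.06 and PHGDH by 3.52 ± 0.05 (171 to 14.9 CPM). CHAC1 (-1.97), SHMT2 (-1.78 ± 0.04), ACTA2 (-1.72 ± 0.07, 2240 to 681 CPM), PYCR1 (-1.63 ± 0.04), COL1A1 (-1.33 ± 0.06, 20500 to 8140 CPM), SLC2A1 (-1.33), SLC7A11 (-0.67), FN1 (-0.23), HIF1A (-0.17) and ALDH18A1 (-0.09) fell, and HK2 (0.89) and CCN2 (0.17) rose. ALDH18A1 was not called without TGFb_Torin1 replicate 1 (-0.07, adjusted p = 0.0579). MTOR and ATF4 were not called (adjusted p = 0.605 and 0.974). INHBE (-6.99 ± 0.35, 20.5 to 0.157 CPM), ADM2 (-5.92 ± 0.32) and the kinase gene ALPK2 (-4.45 ± 0.23) fell the most beside these. The largest increases were of EFCAB12 (4.07 ± 0.22), the nuclear receptor NR4A2 (3.49 ± 0.13), the chemokine CXCL6 (3.41 ± 0.21), DLL4 (3.26 ± 0.15), the prostaglandin synthase PTGS2 (3.21 ± 0.62) and YPEL1 (2.97 ± 0.14). The test called 8615 genes, 4176 raised and 4439 lowered, 1323 of them by at least 2-fold.

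Camera called 17 of 31 lists for Torin1 under TGF-beta, and 8 held with an estimated correlation. Endoplasmic reticulum chaperones fell in 16 of 17 cases (median -1.03, camera adjusted p = 1.64e-10), with HERPUD1, of protein degradation, at -1.45 ± 0.04 and CALR at -1.12 ± 0.03. Aminoacyl-tRNA synthetases gave 2 raised and 18 lowered of 20 (adjusted p = 7.95e-10), with WARS1 at -2.19 ± 0.03 and MARS1 at -2.07 ± 0.04. Serine genes fell in 8 of 12 cases (adjusted p = 1.51e-05), proline genes gave 1 raised and 10 lowered of 12 (adjusted p = 5.01e-05), and stress targets 3 and 13 of 20 (adjusted p = 1.2e-05). Collagen-modifying genes gave 2 and 18 of 20 (adjusted p = 1.63e-07), with SERPINH1, a collagen chaperone, at -2.08 ± 0.04 and P4HA1 at -1.89 ± 0.05. These counts were the same adjusted over the list alone. Ribosome biogenesis genes gave 1 and 15 of 20, 2 and 15 adjusted over the list alone (adjusted p = 5.01e-05), and FOXO targets rose in 13 of 15 cases and fell in 1 by either count (adjusted p = 5.15e-06), with FBXO32 at 2.18 ± 0.04. Transporters gave 2 and 11 of 14 by either count (adjusted p = 1.51e-05, adjusted p = 0.0578 with an estimated correlation). Contractile genes gave 2 and 17 of 20, 2 and 18 adjusted over the list alone (adjusted p = 6.24e-07, adjusted p = 0.0706 with an estimated correlation). Matrix genes gave 3 and 14 of 22 by either count (adjusted p = 0.00507, adjusted p = 0.355 with an estimated correlation). Glycolysis genes gave 4 and 15 of 20 by either count (adjusted p = 0.00134, adjusted p = 0.137 with an estimated correlation). Ribosomal proteins rose in 19 of 32 cases, 20 adjusted over the list alone (adjusted p = 0.00316, adjusted p = 0.57 with an estimated correlation). SMAD targets were not called (9 raised, 5 lowered of 20, 10 and 5 adjusted over the list alone, adjusted p = 0.325).

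With Torin1 present, TGF-beta still raised the myofibroblast genes, while several stress and amino acid genes fell. CCN2 rose by 4.12 ± 0.05 in log2 (n = 4 libraries per group), ACTA2 by 2.54 ± 0.07, COL1A1 by 2.30 ± 0.06, ALDH18A1 by 2.04 ± 0.03 and FN1 by 1.54. PYCR1 (1.21 ± 0.04), CHAC1 (1.14), MTHFD2 (0.89), HIF1A (0.64), MTOR (0.46) and PSAT1 (0.36 ± 0.13, adjusted p = 0.0332) rose. PSAT1 lost its call without Torin1 replicate 1 or 3 or TGFb_Torin1 replicate 1, 2 or 4 (0.25 to 0.36, adjusted p = 0.0589 to 0.142). DDIT4 (-1.6 ± 0.12), SLC7A5 (-1.30), TRIB3 (-0.98 ± 0.06), SLC7A11 (-0.77), PHGDH (-0.59 ± 0.05), HK2 (-0.38) and SHMT2 (-0.17) fell. ASNS (0.00 ± 0.09), SLC2A1 and ATF4 were not called (adjusted p = 0.0719 to 0.981). TSPAN2 (8.72 ± 0.13) and PRG4 (8.14 ± 0.18, 9.04 without Torin1 replicate 4) were among the largest increases. MDFI went from 0.0713 to 21.1 CPM, ACTC1, cardiac actin, from 0.0476 to 18.7 CPM and TYRP1 from 0.0243 to 5.96 CPM. ADH1B (-4.49 ± 0.07), BCL2A1 (-4.31 ± 0.30), ADH1A (-4.28 ± 0.38), PLPPR4 (-4.26 ± 0.19), DHRS13 (-4.11 ± 0.24) and THBD (-3.87 ± 0.24) fell the most. The test called 8695 genes, 4304 raised and 4391 lowered, 2206 of them by at least 2-fold. SMAD targets gave 17 raised and 1 lowered of 20, 17 and 2 adjusted over the list alone (camera adjusted p = 3.03e-11), the 1 call of 12 that held with an estimated correlation. Matrix genes gave 20 and 2 of 22 by either count (camera adjusted p = 8.05e-12, adjusted p = 0.0696 with an estimated correlation). Contractile genes gave 19 of 20 raised by either count (camera adjusted p = 8.05e-12, adjusted p = 0.0662 with an estimated correlation). Serine genes (5 and 5 of 12 by either count, adjusted p = 0.991), transporters (6 and 8 of 14 by either count, adjusted p = 0.897) and stress targets (6 and 9 of 20, 6 and 10 adjusted over the list alone, adjusted p = 0.333) were not called.

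The TGF-beta effect differed with Torin1 in 5228 genes. SLC7A5 had an interaction of -5.56 ± 0.12 in log2 (n = 4 libraries per group), ASNS of -4.64 ± 0.11, PSAT1 of -4.06 ± 0.16, TRIB3 of -3.95 ± 0.09, MTHFD2 of -3.20 ± 0.13, DDIT4 of -3.16 ± 0.16 and PHGDH of -3.09 ± 0.07. SGMS2 (-5.32 ± 1.6, -6.61 without UT replicate 4) and ADM2 (-4.08 ± 0.56) were also among the lowest, and SGMS2 was not called without Torin1 replicate 3 (-4.00, adjusted p = 0.0766). CHAC1 (-2.66), SHMT2 (-1.84 ± 0.06), ACTA2 (-1.55 ± 0.09), PYCR1 (-1.36 ± 0.06), SLC7A11 (-1.25), SLC2A1 (-1.09), CCN2 (-0.64 ± 0.06), FN1 (-0.46) and HIF1A (-0.31) had lower and HK2 (0.23) had a higher TGF-beta effect with Torin1. HK2 lost its call in 11 of the 16 fits that leave out a library (UT replicates 1, 2 and 3, TGFb replicates 1, 2 and 4, Torin1 replicates 1 and 3, TGFb_Torin1 replicates 1, 2 and 3, adjusted p = 0.055 to 0.0816). ATF4, ALDH18A1, COL1A1 and MTOR were not called (adjusted p = 0.238 to 0.653). On the higher side were EFCAB12 (2.61 ± 0.30), IFIH1, a sensor of viral RNA (2.51 ± 0.29), and ACACB, of fatty acid metabolism (2.19 ± 0.10), and, with a large error, COL10A1 (2.99 ± 0.83). CCN1, with 0 reads in 3 of the 4 Torin1 libraries, was also called higher. It lost its call without UT replicate 3 or 4, TGFb replicate 3 or 4, Torin1 replicate 1, 3 or 4 or TGFb_Torin1 replicate 1, 2 or 3 (adjusted p = 0.0501 to 0.0923). Of the 5228 genes, 2468 had a higher and 2760 a lower TGF-beta effect with Torin1, 719 by at least 2-fold, and length offsets gave 3018. Camera called 17 of 31 lists, and 10 held with an estimated correlation. Aminoacyl-tRNA synthetases gave 1 higher and 19 lower of 20 (adjusted p = 2.34e-15), stress targets 1 and 15 of 20 (adjusted p = 5.42e-10), endoplasmic reticulum chaperones 16 lower of 17 (adjusted p = 1.09e-10), serine genes 7 lower of 12 (adjusted p = 2.5e-07), proline genes 1 and 8 of 12 (adjusted p = 3.24e-05) and transporters 1 and 8 of 14 (adjusted p = 6.01e-07), the same adjusted over the list alone. Ribosome biogenesis genes gave 16 lower of 20, 17 adjusted over the list alone (adjusted p = 6.02e-09), and collagen-modifying genes 1 and 13 of 20, 2 and 17 adjusted over the list alone (adjusted p = 5.01e-08). Contractile genes gave 13 lower of 20 by either count (adjusted p = 6.01e-07, adjusted p = 0.0709 with an estimated correlation). Matrix genes gave 2 and 9 of 22, 2 and 12 adjusted over the list alone (adjusted p = 0.00462, adjusted p = 0.316 with an estimated correlation).

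Genes raised by TGF-beta in one experiment were compared with genes lowered by the inhibitor or siRNA in the other, over the 14136 genes tested in both. The Fisher tests and the interval below take genes as independent, which they are not, and hold no spread between libraries. Of 1569 genes raised by TGF-beta in control siRNA cells, 1009 (64.31%, 95% interval 61.88 to 66.68) were lower with Torin1 under TGF-beta, against 26.62% of the remaining genes (Fisher exact p = 8.13e-187). These were 403 of 706 (57.08%) with length offsets, against 21.61% of the remaining genes in that fit. With only the groups compared in the fit they were 1398 of 2259 (61.89%), against 24.9%. Without siATF4 replicate 3 they were 1416 of 2326 (60.88%), against 24.63%. At a change of at least 2-fold in both they were 85 of 350 (24.29%), against 2.553%. These shares count decreases of any size, and the median change of the 1569 genes with Torin1 under TGF-beta was -0.349 in log2. In the Torin1 experiment the 350 genes had a median TGF-beta effect of 2.45 without and 2.14 with Torin1. The effect was smaller in absolute size with Torin1 for 68.6% of them. Of 4625 genes raised by TGF-beta in the Torin1 experiment, 84 (1.82%) were lower with the ATF4 siRNA under TGF-beta, against 0.158% of the remaining genes (Fisher exact p = 7.03e-27). Those 84 became 42, 39 and 47 without siControl_TGFb replicates 1, 2 and 3. They became 42, 40 and 44 without siATF4_TGFb replicates 1, 2 and 3. Without siATF4 replicate 3 they were 272 (5.84%), against 1.396% of the remaining genes in that fit. They were 27 with length offsets, 216 with only the groups compared in the fit and 154 in DESeq2. At a change of at least 2-fold in both they were 16 of 1187 (1.35%), against 0.0386% of the remaining genes. The 1187 genes had a median TGF-beta effect of 0.70 in log2 in control siRNA cells and 0.69 in ATF4 siRNA cells. Among 99 genes lowered by the ATF4 siRNA under TGF-beta, 80 were also lowered by Torin1 under TGF-beta, where 30.49 would overlap by chance (Fisher exact p = 8.88e-25). Genes outside the overlap were ATF4, with 0.01 under Torin1, MMP1, a collagenase (-0.83 ± 0.15 with the siRNA, 1.83 ± 0.10 with Torin1), MMP11 (-0.81 and 1.25), ENC1 (-0.50 and 1.09) and others. MMP1 was not called with the siRNA after leaving out any 1 of the 6 libraries compared (adjusted p = 0.12 to 0.161). The overlap was 39 of 44, 38 of 42 and 45 of 52 genes without siControl_TGFb replicates 1, 2 and 3. It was 41 of 49, 38 of 47 and 45 of 53 without siATF4_TGFb replicates 1, 2 and 3. Without siATF4 replicate 3 it was 245 of 407, a lower share (60.2%) than in the main fit (80.81%), where 124.2 would overlap by chance without that library. It was 26 of 34 with length offsets, 187 of 282 with only the groups compared in the fit and 143 of 197 in DESeq2. Over all 14136 genes, fold changes of the siRNA and of Torin1 under TGF-beta had a Pearson correlation of 0.07 across genes. TGF-beta fold changes in the Torin1 experiment and in control siRNA cells had one of 0.6 across genes, which are not independent replicates, and of 2736 genes called in both, 98.2% moved in the same direction.

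**Figure D4:**
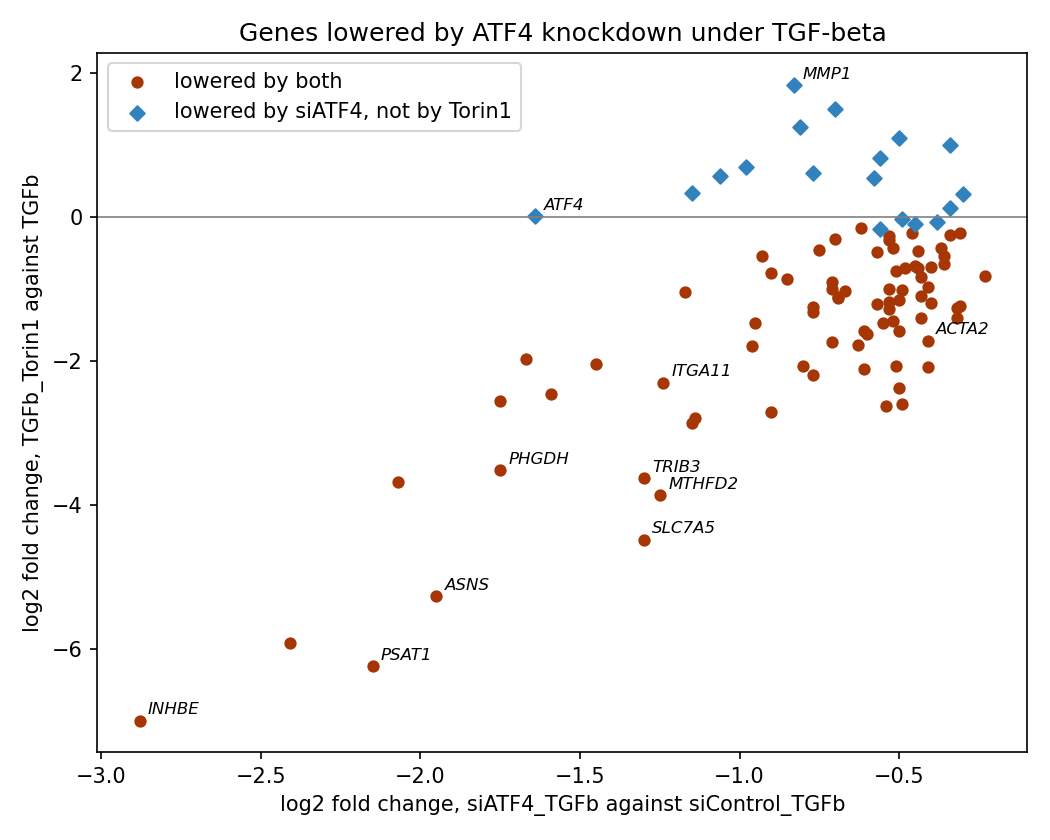
Log2 fold changes under TGF-beta with the ATF4 siRNA (horizontal) and with Torin1 (vertical) for genes lowered by the siRNA. Each point is a gene, and 80 of the 99 genes lowered by the siRNA were also lowered by Torin1. ENSG00000256500 (-10.27 with the siRNA, -0.02 with Torin1) is among the 99 but is not drawn.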

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

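Tests chosen after the results were seen are the 2 on long transcripts, the bound used for a swapped label, the one on a weaker siRNA response, the one on library scaling as a whole pattern and the one on spread added by siATF4 replicate 3, as were the fits without that library for comparisons it is not part of and for the gene lists. The TGF-beta effect differed with Torin1 in 5228 genes and with the ATF4 siRNA in 2 genes, a difference between groups in each case. TGF-beta raised 264 genes without Torin1 that it lowered with it, and lowered 255 that it raised with it. Among transcripts outside GENCODE 29, a part of the files on which the gene tests did not report, TGF-beta changed 394 in the Torin1 experiment (201 raised, 193 lowered) and the ATF4 siRNA under TGF-beta changed 1 (ENST00000697799, 10.9 ± 6.1 CPM in siControl_TGFb and 0 CPM in siATF4_TGFb, against 11.2 ± 1.71 CPM in siControl and 16.6 ± 3.66 CPM in siATF4 without TGF-beta).

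siATF4 replicate 3 had 2001 of 7779 genes over 0.5 log2 units from replicates 1 and 2, against at most 197 in a library of another siRNA group. Loss of long transcripts fits part of this (Spearman -0.767 across genes), but 699 genes stayed over the limit once the length trend was taken out, which argues against it as the whole difference. RNA from other cell types is argued against by 0 of 42 markers that reached 5 CPM in this library alone. The 42 include CD68 (median 160 CPM in the siRNA experiment) and CALB2 (19.8 CPM). Such genes, over the limit in other libraries too, could not count. A swapped label is argued against by the 99 genes lowered by the siRNA under TGF-beta, where this library lay at -0.02 from siATF4 replicates 1 and 2 and at -0.44 from siControl; a bound of over 0.5 from siControl written beforehand was not met, and one of 3 standard deviations (SD 0.032) replaced it after the values were seen. The same -0.02 and -0.44 argue against a weaker response to the siRNA, and a different response of other genes in this library stays open as untested.

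TGF-beta changed 9769 genes in the Torin1 experiment and 2914 in control siRNA cells. Depth and number of libraries are argued against as the whole difference by the 8170 genes called after thinning the Torin1 experiment to 3 libraries per group and 10.2 M reads. Spread from siATF4 replicate 3 is argued against as the whole difference by the 4593 genes called without it. Across genes called in both, fold changes in control siRNA cells had a slope of 0.62 (95% interval 0.59 to 0.64) on those of the Torin1 experiment. The interval comes from resampling genes and holds no spread between libraries or experiments. A smaller response in control siRNA cells goes with this slope. Whether transfection, culture or the cells used lie behind it stays open as a hypothesis, since the labels do not say whether the experiments shared cells.

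Genes with opposite TGF-beta effects included SLC7A5 (4.26 without and -1.3 with Torin1), TRIB3 (2.96 and -0.98), DDIT4 (1.56 and -1.6), PHGDH (2.5 and -0.59), SLC1A5 (0.72 and -1.39), SESN2 (1.38 and -0.59) and DDIT3 (0.97 and -0.87). Independent effects would give 1350 genes raised without and lowered with Torin1, and 20 of the 264 changed by at least 1.5-fold in both. Library scaling is argued against as the whole pattern because no pair of shifts of up to 2-fold, 1 for each comparison, left under 137 genes opposite (474 unshifted by the stricter limit used for this test, 43 with shifts of up to 4-fold), and stays open for a part, since the genes raised without and lowered with Torin1 (median -0.27 with it after centring, upper quartile -0.17) were chosen for lower values. Transcript length is argued against as the whole pattern because 88.2% kept opposite signs of at least 0.1 log2 units after its trend was taken out, against 95.8% before. The genes were chosen for opposite signs, and fold changes ran only weakly with length (Spearman 0.016 without and 0.155 with Torin1). A TGF-beta effect on these genes that depends on mTOR, the explanation the design gives, also stays open as untested, and knockdown of MTOR would test it.

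Splits of the same libraries into other groups of the same size gave these counts. Every other split of a 2-group comparison mixes both groups, so a treatment effect adds to its spread. Low counts in those splits therefore do not measure false calls. In the Torin1 experiment 1 of 35 splits, the real one, called as many genes for TGF-beta (9769, highest other 1), Torin1 untreated (5978, highest other 34), Torin1 under TGF-beta (8615, highest other 1) and TGF-beta with Torin1 (8695, highest other 1). In the siRNA experiment 10 splits are too few: TGF-beta in siControl called 2914 (highest other 1), siATF4 untreated 45 (1), siATF4 under TGF-beta 105 (1) and TGF-beta in siATF4 3050 (2), with 1 split as high, the real one, each time. For the interactions, 100 splits gave 4 as high for the ATF4 siRNA (real 2, highest other 699) and 1 for Torin1 (real 5228, highest other 4389). For the interactions, a split can keep treated and untreated libraries apart in some groups and mix them in others. It then leaves a TGF-beta effect in the interaction, so these counts cannot serve as a test of chance. Which splits gave the highest counts was not examined.

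In the Torin1 experiment a library lay far from the others of its group in 37 of 532 Dixon tests, where chance flags about 1 in 20 groups (26.6 expected). TGFb replicate 3 had 22.5 M reads (others 21.4), and Torin1 replicate 1 had 4.9% mitochondrial reads (others 4.24 to 4.33). In UT, replicate 1 had 37.4 CPM of DDIT4, 15000 of FN1, 17 of NR4A2, 1100 of SPARC and 183 of XPOT, replicate 2 had 5.53 of DNER and 0.0422 of TYRP1 (others 0), and replicate 4 had 0.0439 of MDFI (others 0). In TGFb, replicate 1 had 1100 CPM of CALR and 2840 of POSTN, replicate 2 had 0.221 of ADH1A (others 0) and 2.05 of CRELD1, and replicate 3 had 82.3 of IGF1, 0 of PTGS2 and 125 of PYCR1. In Torin1, replicate 1 had 92.5 CPM of SRXN1, replicate 2 had 2.99 of AIMP1, 0.514 of CCN1 and 1.07 of CRELD1 (others 0 for these 3), 60.7 of CPNE1, 0.14 of MDFI and 237 of STC1, replicate 3 had 24.1 of PHGDH, and replicate 4 had 1820 of COL1A1 and 0.958 of PRG4. In TGFb_Torin1, replicate 1 had 38.5 CPM of GDF10, 143 of NQO1 and 73.7 of SRXN1, replicate 2 had 13.4 of SESN2, and replicate 3 had 11.2 of CBS and 0.367 of CRELD1 (others 0). TGFb_Torin1 replicate 4 had 4440 CPM of CALD1, 5.32 of DDIT4, 2.35 of SLC6A9 and 2440 of SPARC.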

How the results depend on the processing

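Fits without siATF4 replicate 3 for comparisons it is not part of, for the overlap and for the gene lists were chosen after the results were seen, and no other setting here was. With 3 or 4 libraries per group, a simulated 1.5-fold change was recovered in 41.8% of 67 genes for TGF-beta in siControl and 77.6% of 67 in the Torin1 experiment. Far fewer genes were changed there than were called in the real data. Replicate numbers did not pair libraries (same-number correlations -0.04 to 0.05 over 18 pairs and -0.07 to 0.1 over 24 pairs). Named genes kept direction and call in 1343 cases in DESeq2 (56 stronger, 2 weaker), 1384 in limma-voom, 1400 with DESeq2 size factors and 11615 with 1 library left out (108 stronger, 352 weaker). With length offsets 1255 did (144 weaker). Of the list results, 230 kept theirs with an estimated correlation (80 weaker) and 220 with fry (74 stronger, 16 weaker). Lists called in neither test count as kept, and the 80 were camera calls that were lost. Camera called 9 to 17 lists per comparison, of which 0 to 12 held with an estimated correlation. The cause was not tested for any change of count below, other than the 2-fold limit and fits with fewer libraries.

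At least 2-fold changes numbered 684 for TGF-beta in siControl, 11 for siATF4 untreated, 21 for siATF4 under TGF-beta, 657 for TGF-beta in siATF4, 1 for its interaction, 2952 for TGF-beta in the Torin1 experiment, 378 for Torin1 untreated, 1323 for Torin1 under TGF-beta, 2206 for TGF-beta with Torin1, 719 for its interaction and 17 for the overlap of siATF4 and Torin1. Length offsets gave 1361 for TGF-beta in siControl, 11 for siATF4 untreated, 35 for siATF4 under TGF-beta, 1405 for TGF-beta in siATF4, 3739 for Torin1 untreated, 3018 for the Torin1 interaction and 26 for the overlap. They reversed MCM4 in TGF-beta in siControl (0.27), RGS5 there (0.11), MARS1 in siATF4 untreated (0.35), and FH in TGF-beta with Torin1 (0.35) and in the Torin1 interaction (0.37). Fits of only the groups compared gave 4463 for TGF-beta in siControl, 1 for siATF4 untreated, 363 for siATF4 under TGF-beta, 1517 for TGF-beta in siATF4 and 187 for the overlap. DESeq2 gave 220 for siATF4 untreated, 232 for siATF4 under TGF-beta, 17 for the siATF4 interaction and 143 for the overlap. That interaction gave 1 without a low-count filter and 0 in limma-voom. A replicate block gave 22 for siATF4 untreated, 61 for siATF4 under TGF-beta, 0 for the interaction and 52 for the overlap.

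Leaving out 1 library gave 2124 to 4593 genes for TGF-beta in siControl, 18 to 233 for siATF4 untreated, 42 to 589 for siATF4 under TGF-beta, 2254 to 3979 for TGF-beta in siATF4, 0 to 8 for the siATF4 interaction and 38 to 245 for the overlap, the highest each time without siATF4 replicate 3. The 245 were 60.2% of the genes lowered by the siRNA in that fit, against 80.81% in the main fit. Of the camera results for lists in the siRNA experiment, 128 were kept without that library, 16 calls were gained, 10 were lost and 1 was reversed. The 1 was the ribosomal protein list in siATF4 untreated, which turned downward (camera adjusted p = 1.11e-07).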
